A study of Homo sapiens with 5 samples.

How the data were processed

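Transcripts were counted in place, cell by cell, in fixed and embedded sections of human bladder tumors with the Xenium Prime gene panel, an assay that decodes single transcripts by repeated imaging of barcoded probes. The series holds 5 tumors with 1 section each. All 5 carry the same group, bladder tumor, so the tumor was the replicate (n = 5), and tumors were described beside each other but never sorted into groups. Every test compared parts of the same section, cell class by cell class or place by place.

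The deposited matrices hold counts, whole numbers of transcripts per feature and segmented cell with no normalization, and the sums per cell matched the deposited cell tables in all 131875 cells. Per the file headers, the cell tables also hold counts by feature type, the position of each cell and its area. The features were 5001 genes, 3291 deprecated codewords, 1067 unassigned codewords, 609 negative control codewords, 40 negative control probes and 21 genomic controls. The authors' processing notes name Seurat 5.1.0, and the version of the decoding software was not stated. Only the 5001 genes were used for the comparisons, and 4993 of them remained after genes that tell the sex of a person were left out. Sections of tumors 1 to 5 held 27596216, 14640723, 28510733, 7779078 and 7792472 gene transcripts.

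Cells with at least 40 gene transcripts were kept, which left 123927 cells and removed 7948. No doublet caller was run, since cells came from image segmentation. Counts were scaled to 500 transcripts per cell and log-transformed. From 2000 variable genes, without the therapeutic target list, 30 principal components and a graph of 15 nearest neighbours were computed, and Leiden clustering was run at resolution 1 (leidenalg 0.10.2, igraph 0.11.9). All 5 tumors were clustered together without batch correction. A cluster took the name of the marker list with the highest mean log2 ratio to the median over clusters, with 20 CPM added. That mean had to be at least 1, with at least 3 markers at a log2 ratio of 1 or more and seen in at least 3% of cells. Clusters that met this for no list were left unnamed. So were clusters with a median depth under 1/3 of that of their tumors and no marker of the list among their 10 leading genes, which decided 0 clusters here, 2 at resolution 2 and 1 with each tumor clustered on its own. Names such as epithelial-like rest on 10 marker lists, of which the panel lacked many genes. It held 11 of 24 epithelial markers, 8 of 20 fibroblast markers and 15 of 22 T and NK cell markers. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for these steps, and matplotlib 3.10.9 for the figures.

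Neighbourhoods were made from the 20 nearest cells. A cell was in an epithelial neighbourhood when at least 60% of them were epithelial-like, and in a stromal neighbourhood when at most 20% were. Unnamed clusters counted as not epithelial. Epithelial-like cells next to stroma had at least 3 fibroblast-like, muscle or endothelial-like cells within 30 µm, and interior cells had none within 60 µm. Fibroblast-like cells near epithelium had at least 3 epithelial-like cells within 30 µm, and far cells had none within 100 µm. Basal-high and luminal-high cells were the upper and lower of 3 equal parts of the epithelial-like cells of each tumor, ordered by mean basal minus mean luminal gene level. Between 13.6 and 24.7% of the epithelial-like cells of a tumor lay within 10% of an SD of the score from a boundary, so these sides are ranges of a score and not cell types.

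For each side of each comparison, raw counts were summed over cells per tumor. A tumor was used when both sides held at least 30 cells. Sums were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM factors, filterByExpr, the tumor as block, two-sided), with Benjamini-Hochberg adjustment at 0.05. The block pairs the parts of one section, which share the tumor by design. Correlations of the 2 sides after removal of the side means ran from 0.248 to 0.884, apart from -0.0811 for tumor 4 in the therapeutic target comparison. Without the block, edgeR called 0 genes in each of the other 5 comparisons and 13 up and 14 down on the target list. Log2 fold changes are given with a standard error (SE) taken from the fold change and its F statistic. Levels are CPM, a scale that divides each gene's summed count by the sum of all genes, averaged over tumors. In the comparison of basal-high with luminal-high cells, the luminal and basal genes that set the score were left out. In all, 6 such comparisons were made. The result for 1 target gene is not reported here.

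Gene lists were tested with limma 3.58.1. Its fry test asks whether the genes of a list move, on balance, one way, and does not compare a list with other genes. The camera test with an estimated correlation between genes compares a list with all other genes, and its p is printed beside the calls, or as a range over the called lists of the target comparison, because no list in any comparison passed it. Of 21 lists, those with at least 4 tested genes entered, and adjustment was over the lists of a comparison. The list of immediate early and stress genes had 3 of 16 genes on the panel and was not tested. Marker lists of all cell classes were tested in the same way, to show transcripts of neighbouring cells. The share of T/NK-like cells was compared between neighbourhoods by an exact sign-flip permutation test.

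Groups, comparisons, lists, thresholds and the rule for naming genes were set before the data were examined. The rule took the 12 genes with the largest change each way among those that passed, had the same sign in every tumor, reached 20 CPM and were at least as high in the tested class as in every other named class. It added up to 4 genes of each called list. Genes named outside that rule are marked as chosen after their values were seen. Alternatives were DESeq2 1.42.0 with its size factors, no filter on low counts, library sizes without TMM factors, no block, at least 100 transcripts per cell, each tumor clustered on its own, resolution 2, stricter distances, narrower score parts, only genes highest in the tested class, and leaving out each tumor. After the unnamed clusters were seen, 3 more were added. They kept cells with no unnamed cell, or with at most 4, among the 20 nearest, and left out epithelial-like cells in clusters of which another tumor held over 80%.

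The tests were tried on simulated sums with the tumors' own gene levels, depths and dispersion, in which 200 genes were changed. Of those changed by a log2 of 1, edgeR recovered 84% in the basal and luminal design, 10% in the stroma-adjacent design, 28% in the T/NK-like design, 24% in the myeloid-like design, 0% in the fibroblast-like design and 0% in the target design. False calls were 3, 0, 2, 0, 0 and 0. Intervals are 95%, exact Poisson for CPM and exact Clopper-Pearson for shares. They cover counting error within one section only, not differences within a tumor. A count of 0 allows up to 3 counts of the total. No reference genome was provided, and no coordinates are given.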

Results

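The data were in situ transcript counts of single cells from sections of 5 bladder tumors, here called tumors 1 to 5. The sections held 29816, 22095, 42825, 16587 and 20552 segmented cells. Median gene transcripts per cell were 709, 512, 551 and 241 in tumors 1 to 4 and lower again in tumor 5, which had 7792472 in all. After cells with fewer than 40 transcripts were left out, 29146, 21784, 41495, 14748 and 16754 cells remained. Depth differed by class. The median was 776 transcripts in epithelial-like cells, 254 in T/NK-like cells, 330 in myeloid-like cells and 379 in fibroblast-like cells. The series title puts lineage and the vulnerabilities tied to it at the centre, so the comparisons address how luminal and basal genes, drug target genes and the cells around the tumor were arranged.

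The 5 sections differed widely in how much epithelium they held. Epithelial-like cells made up 38.5% ± 28.4 (SD, n = 5) of cells, with 72.6% in tumor 3 (95% interval 72.2 to 73.0) and 2.91% in tumor 4 (2.64 to 3.19). Endothelial-like cells (7.59% ± 2.16), myeloid-like cells (7.71% ± 4.34), T/NK-like cells (6.06% ± 1.42) and fibroblast-like cells (6.04% ± 2.18) were present in every section. Muscle or pericyte-like cells (1.51% ± 1.79), B-like cells (1.44% ± 2.71) and plasma-like cells (0.612% ± 0.793) were scarcer. Tumor 1 held most of the B-like cells, at 6.28% (6.0 to 6.56). No cluster was named mast or neural, so 0 of 14748 cells to 0 of 41495 cells had these names. Clusters that fit no marker list made up 48.2% of tumor 2 (47.5 to 48.9), 69.9% of tumor 4 (69.2 to 70.7) and 34.4% of tumor 5 (33.7 to 35.2). In tumors 1 and 3 they made up 0.106 and 0.0916%. Most of these cells carried liver genes such as APOB, AHSG and C9, which are described further below as values of their own.

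**Figure D1:**
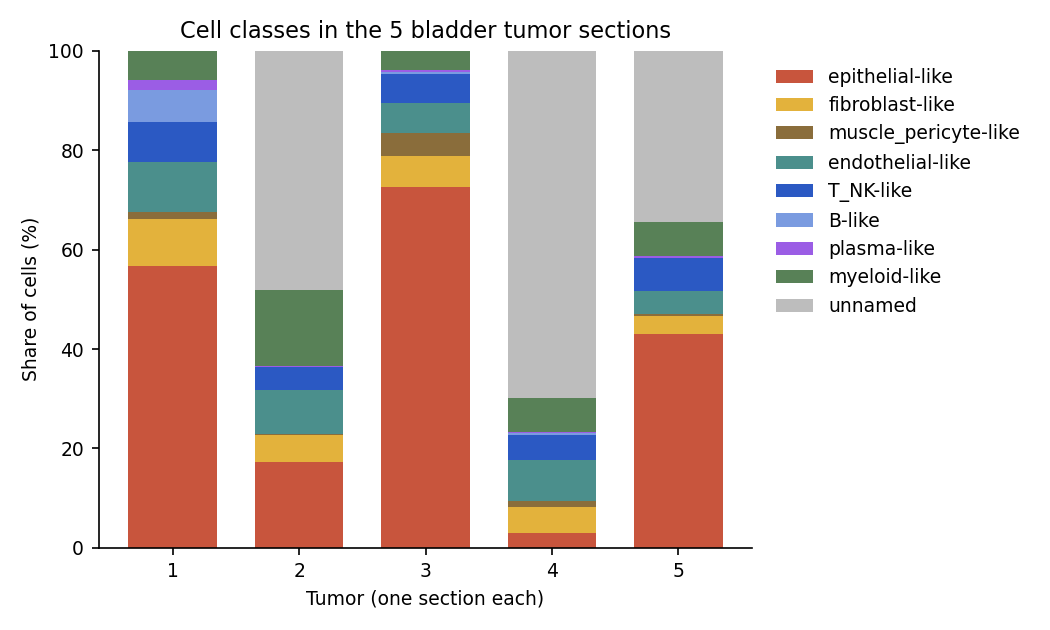
Share of cells (percent) per cell class, with 1 stacked bar for each of 5 tumors. Unnamed clusters reached 69.9% in tumor 4 and stayed under 1% in tumors 1 and 3.

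Epithelial-like cells of the 5 tumors carried different mixes of luminal and basal genes. Luminal genes, which mark differentiated urothelium, summed to 14671 ± 3252 CPM (SD, n = 5), with the highest level in tumor 2 (17840) and the lowest in tumor 5 (9625). Basal genes summed to 4424 ± 2325 CPM. Tumors 3, 4 and 5 had 6824, 5471 and 5955 CPM of them, and tumors 1 and 2 had 2080 and 1790. TP63, a transcription factor of basal urothelium, was at 1022 CPM in tumor 5 (992 to 1053), 677 in tumor 3 and 2.97 in tumor 1 (2.28 to 3.8). KRT20, a keratin of umbrella cells, was at 1941 CPM in tumor 1 (1922 to 1959) and 1458 in tumor 5, but at 5.57 in tumor 2 and 2.82 in tumor 3. In tumor 4 no KRT20 transcript was counted, which allows up to 15.2 CPM. UPK1A, a uroplakin of the urothelial surface, reached 9106 CPM in tumor 2 and 66.4 in tumor 5, and at most 2228 outside tumor 2. It belongs to the luminal list and made up 9106 of the 17840 CPM of tumor 2, so the top rank of that tumor rests on this gene.

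Other programmes also set single tumors apart. The proliferation list was at 14445 CPM in tumor 2 and 11709 in tumor 5, against 3065 to 7622 in the other tumors. The hypoxia and glycolysis list reached 46856 CPM in tumor 4 and 6202 to 12343 in the others. Tumor 5 had 14443 CPM of interferon response genes, against 2741 to 4259. Squamous, neuroendocrine and EMT genes summed to means of 40, 372 and 532 CPM. These lists are shorter, with 5, 11 and 10 genes on the panel, against 27, 16 and 19 for proliferation, hypoxia and interferon. In the EMT list, CLDN7, which was highest in epithelial-like cells, made up 403 of the 532 CPM, so that level mostly reflects this gene. The squamous mean was 25.2 without tumor 5, and the neuroendocrine mean was 205 without tumor 4 and its 429 epithelial-like cells. In tumor 4, ENO2 alone made up 1018 of the 1038.5 CPM of the neuroendocrine list. Genes that led a single tumor were MUC5AC, a gastric mucin, at 1417 CPM in tumor 1 and CYP1A1, a target of the aryl hydrocarbon receptor, at 12554 in tumor 2. BMP7 was at 519 CPM in tumor 3, CA9, a hypoxia-induced carbonic anhydrase, at 3187 in tumor 4, and FABP7 and CCND2 at 1531 and 2753 in tumor 5. These are values of single sections, and no difference between tumors was tested. The panel held 13 of 26 luminal, 11 of 22 basal and 5 of 24 squamous genes, and of the 429 epithelial-like cells of tumor 4, 408 lay in clusters made up mainly of tumor 3 cells.

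**Figure D2:**
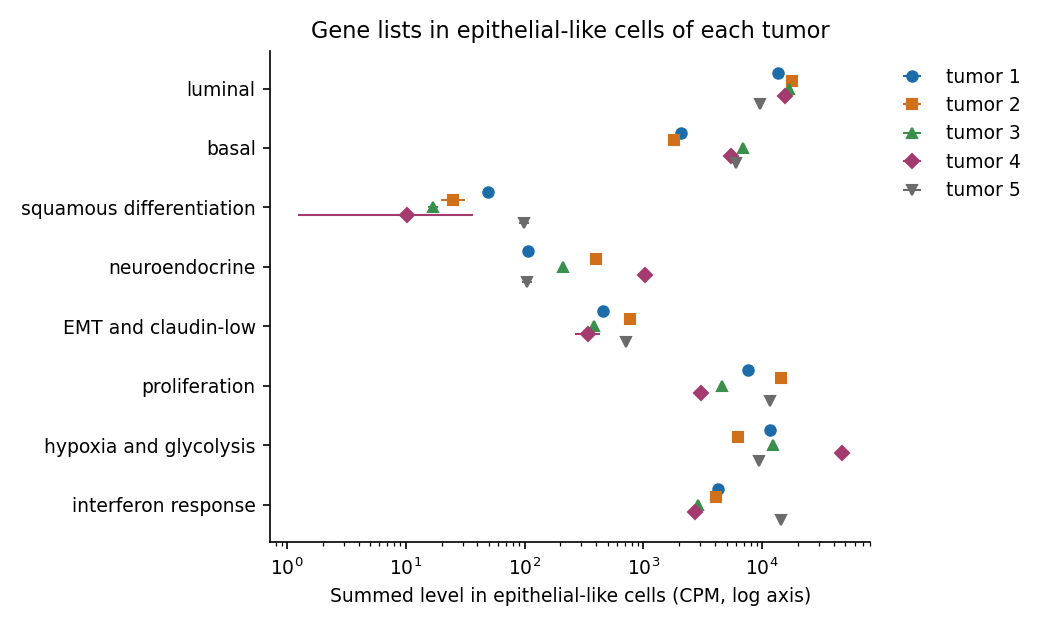
Summed level of 8 gene lists in epithelial-like cells (CPM, log scale) for each of 5 tumors, with exact Poisson intervals. Hypoxia and glycolysis genes stood at 46856 CPM in tumor 4, and interferon response genes at 14443 CPM in tumor 5.

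Genes that drugs in use or in trials are aimed at were compared between epithelial-like cells and all other named cells of the same section (5 tumors). Of 39 tested, 12 were higher in epithelial-like cells and 15 lower; adjusted over the list alone, 14 were higher and 15 lower. Growth factor receptors led the first group. ERBB2 was at 1265 against 191 CPM (log2 fold change 3.13, SE 0.37, adjusted p = 0.0020), higher in 5 of 5 tumors. FGFR3 (3.35, SE 0.67), ERBB3 (2.85, SE 0.48) and the luminal regulator PPARG (2.83, SE 0.51) were also higher in 5 of 5. FGFR3 had its smallest log2 ratio in tumor 2 (1.09), where 219 epithelial-like cells lay in clusters made up mainly of tumor 3 cells. On the log scale from the other epithelial-like cells of tumor 2 (0) to tumor 3 (1), their FGFR3 level was at 0.962. FGFR3 differed at least 8 times between the 2 ends of this scale, with 20 CPM added. The 219 cells held 254770 transcripts, against 2620075 in the other epithelial-like cells of tumor 2. The rise of FGFR3 in tumor 2, and so the count of 5 of 5, may thus rest largely on the 219 cells. The ratio of tumor 2 without them was not computed. The cell cycle and replication genes TOP2A (2.13), CDK4 (1.38) and TOP1 (0.69) and the growth factor gene VEGFA (2.41) rose in 5 of 5. Log2 ratios were small for CDK4 in tumor 1 (0.077) and for TOP1 in tumors 4 and 5 (0.091 and 0.077). The checkpoint ligand gene VTCN1 (2.45), CD276 (1.00) and PRMT5 (0.90) were higher in 4 of 5, and EZH2 (1.11) in 3 of 5. TOP1, CD276 and PRMT5 were higher in another named class than in epithelial-like cells. Ratios per tumor use CPM without TMM factors. Genes higher in the other cells, which were taken as 1 pool and not class by class, were in part immune checkpoint genes. They included PDCD1 (-4.56, SE 0.78), CTLA4 (-4.91, SE 0.91), TIGIT (-4.83), LAG3 (-2.55), HAVCR2 (-3.94), CD274 (-2.50), PDCD1LG2 (-4.18) and ENTPD1 (-2.55), each lower in epithelial-like cells in 5 of 5 tumors. KDR, the main receptor for VEGF, was at 6.59 against 831 CPM (-6.46), and FAP, AXL, FGFR1, ESR1 and CDK6 were lower as well.

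Among the 12 target genes that did not pass were EGFR (1.22, SE 0.46, adjusted p = 0.070), NECTIN2 (0.73, adjusted p = 0.068), AURKA, MUC16, MET, FGFR2, CD47 and PVR. Levels in epithelial-like cells varied between tumors by as much as many of these contrasts. FGFR3 ran from 264 CPM in tumor 2 to 3409 in tumor 4, ERBB2 from 500 in tumor 5 to 2510 in tumor 2, and ERBB3 from 500 in tumor 5 to 3550 in tumor 1. MTAP, an enzyme of methionine salvage, was at 325, 386 and 271 CPM in tumors 1, 2 and 5, at 2.29 in tumor 3 (1.74 to 2.97) and 5.07 in tumor 4 (0.128 to 28.2). Other named cells of tumors 3 and 4 had 228 and 174 CPM of MTAP. The value of tumor 4 is 1 transcript, and 408 of its 429 epithelial-like cells, with 0 MTAP transcripts, lay in clusters made up mainly of tumor 3 cells. The low MTAP of tumors 3 and 4 may thus not be 2 separate findings. In tumor 2, 219 cells in such clusters held 1 MTAP transcript, and the others had 424 CPM. The FGFR3, ERBB2 and ERBB3 levels of tumors 2 and 4 include these cells too.

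Beside the targets, 10 of 13 luminal genes (fry adjusted p = 0.0071) and 21 of 27 proliferation genes (0.010) were higher in epithelial-like cells, as were 10 of 11 epithelial markers that named them. The luminal result is largely not separate from these. KRT20, UPK1A, UPK2 and UPK3A are also among the markers that named the cells, and PPARG, ERBB3 and FGFR3 are target genes given above. Lists that mark other cells fell, with all 9 cytotoxicity genes, 14 of 16 extracellular matrix genes and 13 of 19 interferon response genes lower (fry adjusted p = 0.0013, 0.0052 and 0.0020). With an estimated correlation, adjusted p = 0.25 to 0.95 over the 16 called lists. Fry called the target list down (0.023) although its median log2 fold change was 0.28, and the neuroendocrine list down (0.044) with a median of 0.07. The scaling moved the median of all genes from 0.10 with TMM to -0.20 without it and -0.36 with DESeq2, which called 9 up and 16 down. Without epithelial-like cells lying in clusters of another tumor, which removes tumor 4, 8 were up and 12 down.

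**Figure D3:**
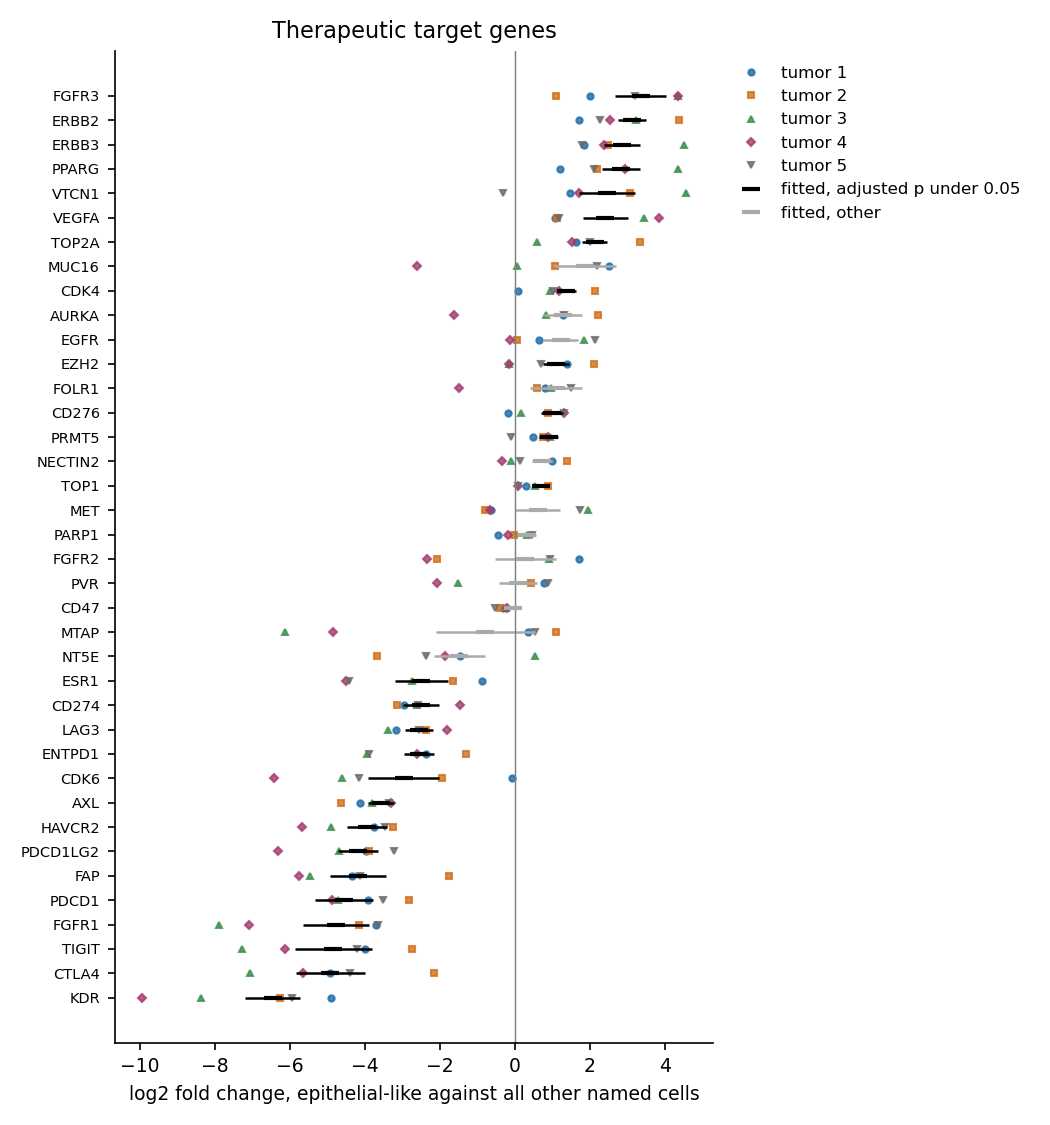
Log2 fold change of 38 target genes in epithelial-like against all other named cells, with 1 point per tumor and the fitted value with SE over 5 tumors. ERBB2, ERBB3, FGFR3 and PPARG lie above 2, and the checkpoint genes PDCD1, CTLA4 and TIGIT under -4.

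Within each tumor, basal-high epithelial-like cells were set against luminal-high ones (5 tumors) to see which programmes go along with the luminal to basal axis. These names are relative within a tumor. The basal-high part began at a score of -0.213, -0.201, -0.0336 and -0.0424 in tumors 1 to 4 and 0.00943 in tumor 5. In tumors 1 to 4 it could thus hold cells with a higher mean luminal than basal level. Basal-high cells carried more transcripts of matrix genes. Of 12 tested extracellular matrix genes 0 passed over all genes and 11 were higher adjusted over the list alone, with a median log2 fold change of 1.45 (fry adjusted p = 0.0051; adjusted p = 0.090 with an estimated correlation). Examples are COL5A1 (1.63, SE 0.21, 81.5 against 25.5 CPM, adjusted p = 0.10, higher in 4 of 5 tumors), POSTN (1.55, SE 0.23, 4 of 5) and COL4A2 (1.31, SE 0.24, 5 of 5), structural or matricellular proteins of the stroma. TGF-beta and Wnt genes followed, with 4 of 14 higher over the list alone (fry adjusted p = 0.0060; adjusted p = 0.090 with an estimated correlation), among them CCN2 (1.92, SE 0.29, 4 of 5 tumors) and LGR5, a Wnt target and stem cell marker (3.50, SE 0.81, 219 against 8.05 CPM, 4 of 5). SNAI2, a driver of epithelial to mesenchymal transition, had 2.11 (SE 0.46, 5 of 5 tumors, adjusted p = 0.12), and its list of 4 genes was called up (fry adjusted p = 0.029; adjusted p = 0.27 with an estimated correlation).

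All 5 macrophage genes were also higher over the list alone (median 1.04, fry adjusted p = 0.0051; adjusted p = 0.10 with an estimated correlation), such as CD163 and STAB1. These matrix and macrophage genes had lower levels in epithelial-like cells than in other classes. The EMT genes SNAI2, ZEB2 and ITGA5, and CCN2, were likewise lower there than in another named class. LGR5 was highest in epithelial-like cells, as was CLDN7 of the EMT list, which went the other way (-0.33). Marker lists of fibroblasts (fry adjusted p = 0.0043), myeloid cells (0.0022), muscle (0.039) and T/NK cells (0.039) moved the same way (adjusted p = 0.066, 0.061, 0.22 and 0.22 with an estimated correlation). As medians over cells, fibroblast, endothelial, T/NK, B, myeloid and neural markers stood at 0 CPM on both sides in all 5 tumors. At least 1 fibroblast marker transcript was seen in 7.69 to 18.2% of basal-high and 0.699 to 11% of luminal-high cells. Muscle marker transcripts were seen in fewer basal-high than luminal-high cells in 5 of 5 tumors (11.2 to 57.5 against 25.2 to 64.2%), and T/NK marker transcripts in fewer in 3 of 5, while myeloid marker transcripts were seen in more in 4 of 5 (all but tumor 3). Basal-high cells held fewer transcripts in 5 of 5 tumors, for example 6052879 against 9970888 from 10039 cells each in tumor 3, which by itself lowers such shares. Epithelial markers, some of which set the score, had lower medians in basal-high cells in 5 of 5 (5682 to 11781 against 10336 to 21967 CPM). Proliferation (27 genes, median 0.16) and hypoxia genes (15 genes, median -0.37) were not called. Over all 3421 genes, edgeR called 1 gene, ADAMTS1, a matrix protease (1.36, SE 0.14, adjusted p = 0.040, 626 against 220 CPM, higher in 5 of 5), named after its value was seen. At an unadjusted p under 0.05 there were 563, and DESeq2 called 128 up and 26 down. Without tumor 1 there were 0 up and 1 down, and without tumor 3, 4 or 5, or at 100 transcripts per cell, 0.

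Epithelial-like cells next to stroma were compared with interior ones (4 tumors, since tumor 4 had too few cells). In tumor 2, 292 of 3758 epithelial-like cells lay in clusters of another tumor, and this comparison did not leave them out. The 2 sides of tumor 2 correlated at 0.323, against 0.810 to 0.884 in tumors 1, 3 and 5. Without cells in clusters of another tumor, edgeR called 2 genes up. Cells at the border carried more POSTN (3.29, SE 0.27, 121 against 12.7 CPM) and COL5A1 (3.52, SE 0.30, 123 against 11.5 CPM), both matrix genes, in 4 of 4 tumors (adjusted p = 0.048 for each). These were the 2 genes that passed of 3592, with 283 at an unadjusted p under 0.05. Of 13 matrix genes, 2 rose over all genes and 10 over the list alone (median 2.12, fry adjusted p = 0.045; adjusted p = 0.24 with an estimated correlation), with COL4A1 at 2.12 (SE 0.29). Macrophage genes had 0 of 6 over all genes and 4 over the list alone (median 1.67, fry adjusted p = 0.045; adjusted p = 0.24 with an estimated correlation). Hypoxia and glycolysis genes went the other way. Of 15 measured, 11 were lower at the border over the list alone, with a median of -1.20, while the list itself did not pass (fry adjusted p = 0.10) and 0 passed over all genes. Over all epithelial-like cells of tumor 2, the list stood at 6202 CPM, and at 4676 without cells in clusters of another tumor. Those cells thus carried more of it, and their part in the border difference was not tested. Basal (10 genes, median 0.04) and proliferation genes (27 genes, median -0.08) had 0 that passed.

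The border cells also carried more fibroblast (fry adjusted p = 0.0064), myeloid (0.018), endothelial (0.036) and muscle markers (0.036), with adjusted p = 0.16 for each with an estimated correlation. POSTN and COL5A1 stood at 50.2 and 46.3 CPM in epithelial-like cells and at 3711 and 6880 in fibroblast-like cells, so neither was among the 951 genes highest in epithelial-like cells of all named classes. Of these 951, 0 passed (59 at an unadjusted p under 0.05). DESeq2 called 42 up and 11 down, edgeR without TMM factors 0, and leaving out any of the 4 tumors gave 0.

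T/NK-like cells inside epithelium were compared with those in stroma (4 tumors, without tumor 4), to see whether lymphocytes among tumor cells differ in state. On the stromal side, 56 of 836 T/NK-like cells of tumor 2 and 280 of 732 of tumor 5 had at most 4 unnamed cells among the 20 nearest. In these 2 tumors the stromal side thus lay mostly in or near unnamed clusters, so the sides also differ in these surroundings. Lower inside were GZMK, a granzyme of memory-like CD8 T cells (-1.89, SE 0.30, 89.6 against 366 CPM, adjusted p = 0.020), and KLRG1, a receptor of differentiated T and NK cells (-1.81, SE 0.32, 132 against 466 CPM, adjusted p = 0.025). GIMAP4 (-1.16, SE 0.26), the interferon-induced GBP5 (-0.80, SE 0.18) and CD99 (-0.66, SE 0.15) fell as well, each in 4 of 4 tumors. These 5 are the called genes at least as high in T/NK-like cells as in every other named class; among all 337 such genes taken alone, 0 passed (62 at an unadjusted p under 0.05), and among the 312 also at least as high as in the unnamed clusters 1 fell. Cytotoxicity genes (9 tested, 0 up, 1 down, fry adjusted p = 0.76) and exhaustion and checkpoint genes (15 tested, 0 up, 0 down, 0.81) were not called. Naive and memory (8 tested) and regulatory T cell genes (7 tested) had 0 that passed. Of 17 interferon genes 1 fell (fry adjusted p = 0.052).

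Genes that rose were mainly those of epithelial cells. Over 2818 genes, 71 rose and 52 fell, with 579 at an unadjusted p under 0.05. Luminal genes rose (5 of 11, fry adjusted p = 0.0028; adjusted p = 0.18 with an estimated correlation), for example UPK3A (3.86, SE 0.54) and UPK2 (3.38, SE 0.69), as did all 8 epithelial markers (0.021; adjusted p = 0.091 with an estimated correlation). Proliferation genes rose (6 of 20, fry adjusted p = 0.049; adjusted p = 0.30 with an estimated correlation), with TOP2A at 1.83 and CCNB1 at 1.95. Of 12 hypoxia genes 1 rose, ALDOA (0.99), and fry called the list up (0.019; adjusted p = 0.68 with an estimated correlation) against a median of -0.14. Macrophage genes fell (4 of 5, fry adjusted p = 0.0026; adjusted p = 0.23 with an estimated correlation), among them CD163 (-1.95) and MRC1 (-2.03). Markers of myeloid, fibroblast, endothelial and plasma cells and of T/NK cells themselves were lower inside epithelium (0.041 each; adjusted p = 0.12 each with an estimated correlation). Of the raised genes, 95.8% had their highest level in epithelial-like cells, against 22.5% of all tested genes, and 30.8% of the lowered ones had it in the unnamed clusters, against 10.3%. Leaving out tumor 2 or 5 gave 0 genes and leaving out tumor 3 gave 57. With no unnamed cell among the 20 nearest, which left 3 tumors, 0 genes passed. With at most 4, which kept 4 tumors, 105 rose and 76 fell.

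**Figure D4:**
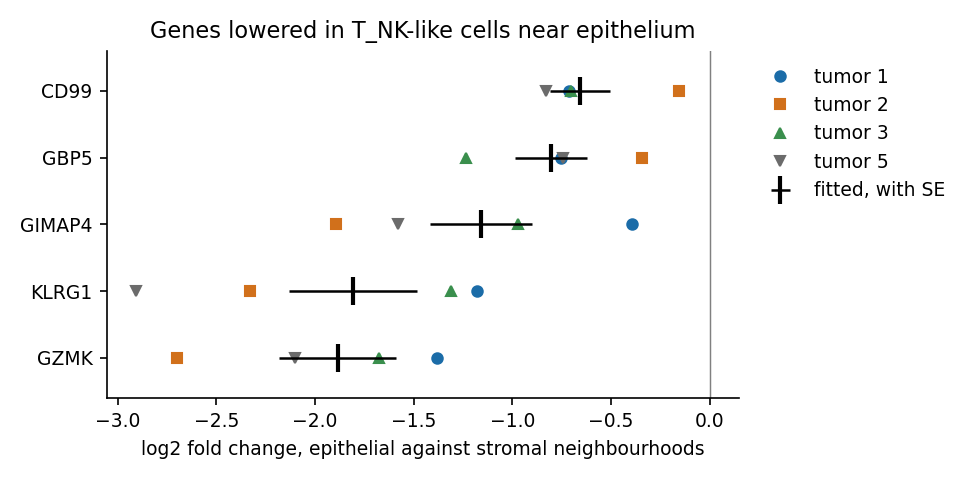
Log2 fold change of 5 lowered genes in T/NK-like cells of epithelial against stromal neighbourhoods, with 1 point per tumor and the fitted value with SE over 4 tumors. GZMK lies at -1.89, KLRG1 at -1.81 and CD99 at -0.66.

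Over all cells, unnamed ones included, the density of T/NK-like cells did not differ in 1 direction. Among cells that were not epithelial-like, their share was higher in epithelial than in stromal neighbourhoods in tumors 2 (13.6 against 5.04%) and 5 (24.2 against 9.63%) and lower in tumors 1 (14.6 against 18.1%) and 3 (15.5 against 25.0%). The mean log2 ratio was 0.44 ± 1.10 (SD, n = 4), with exact permutation p = 0.5, two-sided; 4 tumors cannot go below 0.125. Of 16602 cells in stromal neighbourhoods of tumor 2, 360 had at most 4 unnamed cells among the 20 nearest, as did 669 of 7603 in tumor 5. In those 360 and 669 cells the T/NK-like share was 15.6 and 41.9%, against 13.8 and 25.4% inside epithelium under the same limit. The higher share inside epithelium in tumors 2 and 5 thus rests on counting stromal cells in or near unnamed clusters. With no unnamed cell among the 20 nearest, which left 34 and 83 stromal cells in tumors 2 and 5, the share was lower inside epithelium in 4 of 4 tumors (mean log2 ratio -0.59 ± 0.19, exact permutation p = 0.125), and with at most 4 it was -0.47 ± 0.27. For myeloid-like cells the ratio was 1.11 ± 0.46, higher in 4 of 4 (exact permutation p = 0.125), and 0.40 ± 0.63 with no unnamed cell near, higher in 3 of 4 (exact permutation p = 0.375), where tumor 2 went from 1.24 to -0.38.

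**Figure D5:**
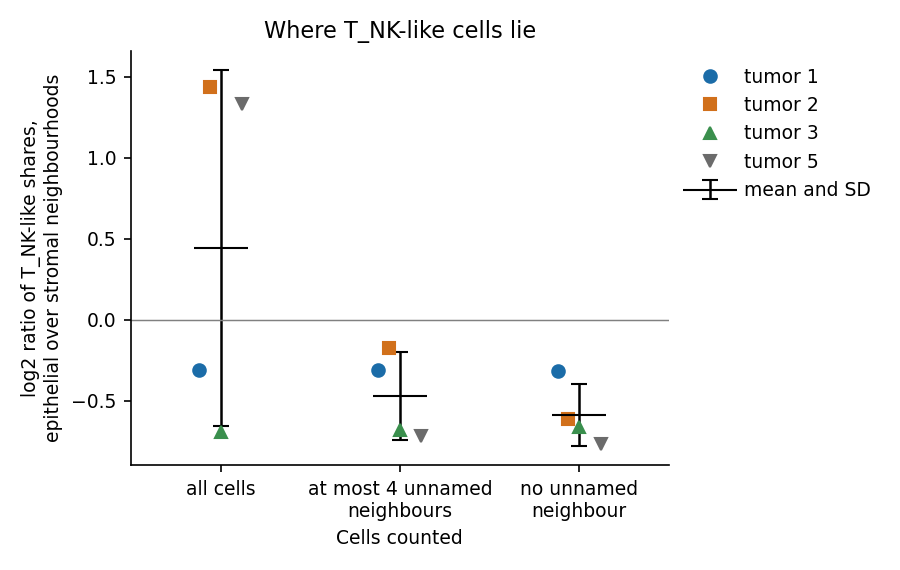
Log2 ratio of the share of T/NK-like cells in epithelial over stromal neighbourhoods, with 1 point per tumor (4 tumors) and the mean with SD, for all cells and for cells with few or no unnamed neighbours. The mean is 0.44 over all cells, -0.47 with at most 4 and -0.59 with no unnamed cell among the 20 nearest.

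Myeloid-like cells inside epithelium (4 tumors) carried less of several macrophage genes than those in stroma. On the stromal side, 158 of 2737 myeloid-like cells of tumor 2 and 116 of 656 of tumor 5 had at most 4 unnamed cells among the 20 nearest. CFP, the complement factor properdin (-3.09, SE 0.37, 64.1 against 577 CPM, adjusted p = 0.037), CD163, a scavenger receptor (-1.45, SE 0.21, 708 against 1823 CPM, adjusted p = 0.047), and CD1D, which presents lipids (-1.40, SE 0.20, adjusted p = 0.047), fell in 4 of 4 tumors. All 3 were highest in myeloid-like cells, and they were also the 3 that passed among the 338 genes of that kind. TREM2, a receptor of lipid-handling macrophages, had 2.65 (SE 0.52, 991 against 252 CPM, 4 of 4 tumors, adjusted p = 0.083), and FOLR2 had -0.93 (adjusted p = 0.087). Of 7 macrophage, complement and lipid genes 1 fell over all genes, and 1 rose and 5 fell over the list alone (fry adjusted p = 0.022, down; adjusted p = 0.21 with an estimated correlation). Monocyte and inflammatory genes (8 tested) had 0 that passed. The 2 sides held different mixes of 3 myeloid-like clusters. The cluster with ITGAX and TREM2 among its 10 leading genes made up 75.4 to 98.9% of the cells inside epithelium and 18.5 to 74.2% of those in stroma. The cluster led by MARCO and CD5L, with CD163 and CFP among the next genes, made up 81.2% of the stromal side in tumor 2, 25.2% in tumor 5 and 0% in tumors 1 and 3, where CFP had -1.68 and -3.43 and CD163 -1.02 and -1.36. The cluster led by F13A1, with MRC1 and FOLR2 among its 10 leading genes, made up 27.7 and 43.7% of the stromal side in tumors 1 and 3, against 1.95 and 24.6% inside, so the mix of clusters differed there as well. MARCO, CD5L, ITGAX and F13A1 were named after their values were seen, and levels within a cluster were not compared.

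Over 2891 genes, 7 rose and 15 fell, and 488 had an unadjusted p under 0.05. Besides CFP, CD163 and CD1D, the lowered genes included the liver products SAA4, PLG, C9 and C8B and the sinusoidal receptor CLEC4M. The raised ones included the urothelial genes UPK3A and MAL, all chosen after their values were seen except UPK3A. Fry called proliferation (0.014; adjusted p = 0.10 with an estimated correlation), luminal (0.032; adjusted p = 0.21 with an estimated correlation) and target genes (0.011; adjusted p = 0.39 with an estimated correlation) up. Epithelial markers rose (0.0070; adjusted p = 0.063 with an estimated correlation), and endothelial (0.019), plasma (0.029) and myeloid markers (0.040) fell (adjusted p = 0.18 each with an estimated correlation). DESeq2 called 48 up and 73 down. Without tumor 5 the count was 0, and it was 43 without tumor 1 and 44 without tumor 2.

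Fibroblast-like cells near epithelium differed from those far from it (4 tumors) in 5 of 2937 genes. The far side lay mostly among unnamed clusters in tumors 2 and 5, where 13 of 898 and 1 of 87 far cells had at most 4 unnamed cells among the 20 nearest, so the 2 sides also differ in these surroundings. PTGIS, the prostacyclin synthase (-2.28, SE 0.25, 90.0 against 390 CPM), and CPS1, a urea cycle enzyme of hepatocytes (-4.17, SE 0.46, 52.0 against 1063 CPM), were lower near epithelium in 4 of 4 tumors. The other 3, named after their values were seen, were AOC3 (-2.93, SE 0.35), the epithelial gene EPCAM (3.98, SE 0.39) and the macrophage gene TREM2 (5.46, SE 0.64, 156 against 1.54 CPM). All had adjusted p = 0.042. CPS1 was higher in the unnamed clusters (2458 CPM) than in fibroblast-like cells (1060). Matrix genes had a median of 1.34, with 0 of 13 over all genes and 1 up over the list alone (fry adjusted p = 0.20), and inflammatory and universal fibroblast genes a median of -0.81 (4 tested, 0 and 2 down over the list alone, 0.34). No gene list was called, while epithelial markers were (fry adjusted p = 0.010, up; adjusted p = 0.10 with an estimated correlation). At an unadjusted p under 0.05 there were 387 genes, and DESeq2 called 33 up and 86 down. Leaving out tumor 2, 3 or 5, or using 100 transcripts per cell, gave 0.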

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

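The tests of other liver cell types, of neighbour transcripts and of dilution were chosen only after the results were seen; the others were set before.

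Single tumors stood far from the other 4 in 15 of 65 sets of 5 values, judged by the gap to the nearest tumor relative to the range. For independent, normally distributed values chance gives about 1 in 20, or 3.25. These sets overlap in part, as VEGFA is in the hypoxia and glycolysis list, and their distribution was not tested. The 3.25 is thus no firm baseline. Genomic control codewords reached 4.98% of the gene level in tumor 4, against at most 1.19% elsewhere. Muscle or pericyte-like cells made up 4.59% of tumor 3 (at most 1.33% elsewhere). B-like cells made up 6.28% of tumor 1 (at most 0.398%) and plasma-like cells 2.02% (at most 0.364%). Myeloid-like cells made up 15.1% of tumor 2 (at most 6.87%).

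In epithelial-like cells, the hypoxia and glycolysis list stood at 46856 CPM in tumor 4 (at most 12343 elsewhere), with ENO2 at 1018 (at most 182) and VEGFA at 3374 (at most 1049). Tumor 5 had 14443 CPM of interferon genes (at most 4259), 455 of FGFR2 (at most 157) and 452 of XBP1, which was at 917 to 1059 in the others. Tumor 2 had 9106 CPM of UPK1A (at most 2228) and 253 of PEG10 (at most 23.2). Tumor 1 had 165 CPM of MUC16 (at most 7.17) and 104 of CDK6 (at most 16.7).

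Unnamed clusters, whose cells were tested in no gene comparison and counted only among the other cells of neighbourhoods and shares, carried hepatocyte genes. They held 48.2% of the cells of tumor 2, 69.9% of tumor 4 and 34.4% of tumor 5, against about 0.1% in tumors 1 and 3. Liver tissue in these sections is a candidate explanation: around the clusters, endothelial-like, myeloid-like and fibroblast-like cells carried sinusoidal, Kupffer and stellate genes, with a lowest median log2 ratio of 1.47 over 3 lists and 3 tumors. Zonation of liver genes left it open, with log2 differences of 0.98, -0.0515 and 0.21 in tumors 2, 4 and 5. Tumor 4 passed the bound of 0.2 set against liver tissue, but by less than the spread over genes (SD 0.53), a criterion added after the value was seen. Urothelial cells that express hepatocyte genes, and free RNA over other cells, also stayed open, each by 1 tumor of 3. Proliferation stood at 0.0578 and 0.0916 of the epithelial level in tumors 2 and 5, inside the bound of 0.25 set against the first for all 3, and at 0.292 in tumor 4, where that level rests on 429 cells. In the unnamed clusters themselves it was 835, 895 and 1072 CPM in tumors 2, 4 and 5. The epithelial level was 14445, 3065 and 11709 CPM, and most of the 429 cells behind 3065 lay in clusters made up mainly of tumor 3 cells. Class markers stood at 0.318 and 0.383 of the named cells' level in tumors 2 and 4, inside the bound of 0.5 set against the second, and at 0.521 in tumor 5.

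Tumors 2 and 4 held epithelial-like cells in clusters made up mainly of tumor 3 cells. In tumor 2 these were 219 cells within 213 by 156 µm. That clustering misplaced cells of tumor 2 was argued against by 49 genes left out of clustering, which lay at a median of 0.986 on the way from tumor 2 (0) to tumor 3 (1). Cells of tumor 3 carried onto the section remain a candidate, since MTAP in them was 0.00927 times that in the other epithelial-like cells (95% interval 0.000234 to 0.0517), 1 transcript in all. In tumor 4, 408 of 429 epithelial-like cells were in such clusters, and all 429 lay at a median of 0.912 over 9 genes, which may reflect carried cells, cells assigned to the wrong section, or a tumor that resembles tumor 3; no test parted these, and no biological explanation was tested.

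T/NK-like cells of epithelial neighbourhoods carried more of many epithelial genes and less of 52 others. Transcripts of neighbouring epithelial cells are a candidate source of the rises: 95.8% of the 71 raised genes were highest in epithelial-like cells, against 22.5% of all tested genes. For the falls, transcripts of other neighbours stay open, since 90.4% of the 52 lowered genes were higher in another class or in the unnamed clusters, but so were 88.9% of all tested genes. Dilution by epithelial transcripts stays open for GZMK, KLRG1, GIMAP4, GBP5 and CD99. They lay under the median of T/NK-high genes (-0.23), but they were picked because they fell. Tested against that median over all 312 T/NK-high genes, the lowest adjusted p of the 5 was 0.105, for GZMK (-1.66 from the median, SE 0.30), which fell in 4 of 4 tumors. A difference between neighbourhoods in which T or NK cells they hold was not tested and stays open.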

How the results depend on the processing

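The alternatives that left out unnamed cells, compared levels with the unnamed clusters, or left out cells in clusters of another tumor were chosen after the data were seen. The target gene count kept within 1.5 times of 27 under every alternative except genes highest in epithelial-like cells (9, from fewer genes tested), and was 21 to 23 with each tumor left out. Of values for single named genes, 966 kept direction and side of the threshold, 196 no longer passed, 59 newly passed and 0 reversed.

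The basal-high count (1) became 154 with DESeq2, and 0 without TMM, without the block, with genes highest in the class (named classes or unnamed clusters too), at 100 transcripts per cell, with each tumor clustered on its own, with sixths of the score, and with no unnamed cell or at most 4 near. The stroma-adjacent count (2) became 53 with DESeq2, 5 with stricter distances, and 0 without TMM, without the block, with genes highest in the class by either definition, at 100 transcripts, with own clustering and with no unnamed cell near. The T/NK-like count (123) became 428 without the filter, 0 without the block, and 0 and 1 with genes highest in the class by either definition. It was 0 with no unnamed cell near, which left 3 tumors, and 181 with at most 4. The myeloid-like count (22) became 121 with DESeq2, 241 without the filter, 0 without the block, 3 and 3 by class level, 36 with own clustering, 52 with stricter distances and 68 with at most 4 unnamed cells near. The fibroblast-like count (5) became 119 with DESeq2, 191 without the filter, 0 without the block, 47 and 8 by class level, 0 at 100 transcripts, 8 with own clustering and 3 with stricter distances, which left 3 tumors. Class levels changed which genes were tested as well as how many. For fibroblast-like cells, 99 of 281 genes highest in the class among named classes had an unadjusted p under 0.05, against 387 of all 2937. Of the 47 called there, 44 fell. The cause of the shifts was not tested. Lists called by camera with an estimated correlation were 0 in the basal-high, 0 in the stroma-adjacent, 0 in the T/NK-like, 0 in the myeloid-like and 0 in the target comparison. With no unnamed cell near, too few tumors were left for a myeloid-like or fibroblast-like test, and for the latter also with at most 4.

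With each tumor left out, counts ran from 0 to 1 (basal-high), 0 to 0 (stroma-adjacent), 0 to 116 (T/NK-like), 0 to 44 (myeloid-like) and 0 to 6 (fibroblast-like). Mean shares ran from 30 to 47.4% (epithelial), 5.17 to 6.66 (fibroblast), 0.740 to 1.86 (muscle), 6.98 to 8.32 (endothelial), 5.53 to 6.40 (T/NK), 0.226 to 1.78 (B), 0.258 to 0.722 (plasma), 5.85 to 8.68 (myeloid), 0 to 0 (mast), 0 to 0 (neural) and 20.7 to 38.2 (unnamed). Clusters that took the mast name held 0.123% of cells with own clustering and 2.04% at resolution 2, where the myeloid share was 5.88% in place of 7.71%. Whether they are mast cells was not tested. The median share of unnamed clusters over the 5 tumors was 34.4%, against 43.0% with own clustering and 47.0% at resolution 2. The T/NK density log2 ratio ran from 0.11 to 0.82 and reversed to -0.59 with no unnamed cell near and -0.47 with at most 4. Stromal neighbourhoods of tumors 2 and 5 then lost most of their cells. Their T/NK-like share was 15.6 and 41.9% with at most 4, against 5.04 and 9.63% when all cells, unnamed ones included, were counted. Tumors 4 and 5 were the shallowest, and the 429 epithelial-like cells of tumor 4 set its floor at 15.2 CPM.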

Other observations

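The test of other liver cell types and the counts of other splits were chosen after the results were seen; the remaining values carry no test.

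The unnamed clusters of tumors 2, 4 and 5 carried genes of secreted liver proteins and liver metabolism. APOB, the core protein of VLDL, stood at 20180, 14390 and 13970 CPM in them, and at 335, 25.3 and 109 CPM in epithelial-like cells of the same tumors. Plasminogen (PLG) was at 13560, 13790 and 7824 CPM, the urea cycle gene CPS1 at 4210, 4192 and 2530, and the nuclear receptor HNF4A at 742, 738 and 885. Over a list of 30 hepatocyte genes, 27 to 29 reached 100 CPM. HAMP, the iron hormone hepcidin, differed between sections, at 202, 3385 and 479 CPM. A small cluster of 123, 328 and 134 cells in these tumors carried bile duct genes, with CFTR at 436, 6569 and 3454 CPM and SOX9 at 1154, 1504 and 2171.

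Cells around these clusters also had a profile of their own. In endothelial-like cells surrounded by them, 14 or 15 of 16 sinusoidal genes were higher than in those away from them, with medians of 2.25, 2.38 and 2.52 on the log2 scale. In myeloid-like cells, 12 or 13 of 13 Kupffer genes were higher (medians 2.10, 2.23 and 1.47), and in fibroblast-like cells 8 to 10 of 12 stellate genes (2.38, 2.41 and 2.05). Such cells may be liver sinusoid around tumor, a hypothesis that the lowest of these medians, 1.47, leaves standing and that the labels do not state. Stromal sides of the comparisons in tumors 2 and 5 hold many of these cells.

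Other splits of the sums, with the tumor as block, were counted for each comparison. For target genes 1 of 100 splits gave 27 genes or more, the real one, and the highest other gave 0. For stroma-adjacent cells it was 1 of 32 (real 2, highest other 0) and for T/NK-like cells 1 of 32 (real 123, highest other 20). For these 3 the share is under 0.05 over splits of any pairing, most of which do not part every tumor's pair of sums as the real one does. Over such splits, chance cannot be excluded for the basal-high count, where 15 of 100 splits gave at least 1 gene (highest other 57), the myeloid-like count (3 of 32, real 22, highest other 56) or the fibroblast-like count (3 of 32, real 5, highest other 176). Splits with 56 to 176 genes may point to a structure of the samples, which was not tested further, and none of them parts every tumor's pair of sums. Among splits that part every tumor's pair of sums, the real one was compared with others that gave at most 0, 0, 0, 2, 2 and 0 genes in the order basal-high, stroma-adjacent, T/NK-like, myeloid-like, fibroblast-like and target. With 16, 8, 8, 8, 8 and 16 such splits, a share under 0.05 cannot be reached.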
